A study of Homo sapiens with 18 samples.

How the data were processed

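The measurements were small RNA sequencing counts of mature miRNAs in 18 libraries of MCF-7 cells, in 3 groups of 6. Per the labels' protocols, cells in 6-well plates received 2.5 µg of plasmid by lipofection, the medium was replaced after 6 h, and miRNA was isolated after 48 or 72 h; libraries were made with the QIAseq miRNA kit, which carries molecular identifiers. The deposited values were raw read counts, 1 for each pair of mature miRNA and precursor, as whole numbers per library. Per the submitters' processing notes, FastQC 0.10.1, Bowtie 1.1.1, edgeR and the build hg19 were used, without their roles or order; the counting tool, the miRBase release and any collapsing of molecular identifiers are not given in the sources used here. If reads were not collapsed, they are not independent molecules, and precision from depth covers counting error only.

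The table held 2822 entries for 2588 mature miRNAs; 170 miRNAs with several precursors had more than 1 entry, up to 11. A read of such a miRNA may be counted under each precursor, so the entry with the largest total was kept for each mature miRNA; this choice was made after the table was seen and is a departure from testing the table as deposited, and the test over all deposited entries was run as an alternative. 410 miRNAs had no count in any library. Total counts per library ranged from 3891732 to 11850181. miRNAs with near-identical sequences (the miR-320 family, miR-1268a and miR-1268b, miR-1260a and miR-1260b) may share reads, and their split is uncertain.

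Groups were taken from the labels. edgeR 4.0.16 was run in R 4.3.3 on the counts with trimmed-mean-of-M-values factors, filterByExpr by group (635 miRNAs kept), and the quasi-likelihood test with group as the only term, all 18 libraries sharing 1 estimate of the spread. P-values were adjusted by the Benjamini-Hochberg method over the miRNAs tested, with a threshold of 0.05. The SE of a log2 fold change is its size divided by the square root of the F statistic. CPM are normalised by the same factors and are given as mean ± SD. 3 comparisons were made: HNRNPA2B1 at 48 h and at 72 h against the control at 48 h, and HNRNPA2B1 at 72 h against 48 h, which is also the test of the difference between the first 2. Totals were compared by two-sided exact permutation tests.

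22 lists of miRNAs (families, clusters, breast cancer groups, fragments of other RNAs, and markers of other cell types) were fixed before the data were examined, as were the tests, most alternatives and the rule for named miRNAs. The exosome-sorted list and the cluster of miR-221 and miR-222 had fewer than 3 tested members and were only counted. The other 20 were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation of 0.01, again with an estimated correlation, and with fry. Named miRNAs were the 8 largest rises and 8 largest falls against control (5 and 5 for 72 h against 48 h) among those past the threshold, with a mean of at least 10 CPM and at least 5 of 6 libraries on 1 side of the reference mean; the 8 most abundant miRNAs; and up to 4 members of each list with the smallest p. Not every list member that the rule allows is named.

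Precursors were located by symbol in the GENCODE annotation of GRCh37, the assembly that hg19 also names; 533 of the 635 (83.9%) were found, and no position is given for the rest. Positions are 1-based, and the GC content was taken from the genome sequence.

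The pipeline was tested on simulated counts with the means, dispersions and sizes of these libraries, with 635 miRNAs per comparison and 200 changed singly. The members of 1 further list were raised 2-fold, which left 420 unchanged. For 48 h against control, edgeR recovered 22.4% of changes of 1.5-fold, 64.2% of 2-fold and 87.9% of 4-fold, with 0 of 420 unchanged miRNAs called. For 72 h against control these were 28.4%, 59.7% and 89.4%, with 4 unchanged miRNAs called, and for 72 h against 48 h 16.4%, 67.2% and 87.9%, with 1. camera passed the 1 list raised 2-fold and none of 21 unchanged lists in each comparison, at both correlation settings; these simulated miRNAs were independent, unlike real clusters.

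Alternatives were relative log expression and upper-quartile factors, total counts alone, DESeq2 1.42.0, limma-voom, no filter, a filter of 10 CPM in 6 libraries, only the groups compared, the replicate number as a block, no fragment list, no 5 most abundant miRNAs, an adjusted p under 0.01, a fold of at least 1.5 and each library left out. Added after seeing the data were a term for the split of 11 and 7 libraries, each side of it alone, the fit without controls 3 and 6 and 72 h replicate 6, and all deposited entries. The sides of that split were not averaged or tested against each other: ranges over the libraries of each side are given, and in the fits it entered only as a term, or as a limit within which the labelled groups were compared. Because the 11 were picked by their 14q32 sums, calls of that cluster within them are not reported, though the total counts of calls include it. Random draws used fixed seeds; 100 splits per comparison and 50 simulations of unchanged groups were made. Figures were drawn with matplotlib. No library was left out of the values reported as results.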

Results

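Mature microRNAs (miRNAs) were counted in MCF-7 cells, an oestrogen-receptor-positive human breast cancer cell line, after transfection with a plasmid carrying HNRNPA2B1 or with the empty plasmid pcDNA 3.1. HNRNPA2B1 is an RNA-binding protein with known roles in splicing, in the processing of some primary miRNAs and in the sorting of RNA into extracellular vesicles. The 18 libraries formed 3 groups of 6: empty plasmid at 48 h (control), HNRNPA2B1 at 48 h and HNRNPA2B1 at 72 h. No 72 h control was among these libraries, and the labels describe the 72 h cells in one place as transiently and in another as stably transfected. The mRNA of HNRNPA2B1 was not measured, so the libraries hold no check of its overexpression. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. Index primer numbers were 1 to 6 at 72 h, 7 to 12 in the controls and 13 to 18 at 48 h, so index order cannot be told from group.

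Total counts ranged from 3891732 to 11850181 per library. They averaged 9124677 ± 1818962 (SD, n = 6) in the controls, 5517009 ± 1470561 at 48 h and 5374286 ± 847190 at 72 h. The controls were deeper than the 48 h libraries (two-sided exact permutation test, p = 0.00649) and the 72 h libraries (p = 0.00433, same exact test; adjusted p = 0.00974 for both over 3 comparisons). miR-21-5p, an abundant miRNA of many carcinomas whose precursor overlaps an exon of VMP1 (GRCh37 chromosome 17, 57918627 to 57918698), made up 40.2 ± 9.25% of the counts in the controls, 43.5 ± 5.42% at 48 h and 34.0 ± 8.60% at 72 h (SD, n = 6 each).

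The largest difference between libraries did not follow the groups. The first principal component held 79.2% of the variance. The 33 tested miRNAs of the imprinted DLK1-DIO3 cluster at 14q32 (GRCh37 chromosome 14, 101335397 to 101532328) summed to 1635 to 3873 CPM, counts scaled to the normalised library total, in 11 libraries and to 14.9 to 146 CPM in the other 7. The 11 were controls 3, 4 and 5, 48 h replicates 4, 5 and 6, and 72 h replicates 1 to 5. Within the 11, controls 4 and 5 and 48 h replicates 4, 5 and 6 lay at a lower level, 1635 to 2080 CPM. Control 3 and 72 h replicates 1 to 5 lay at an upper level, 3444 to 3873 CPM. Fits with a term for the split or within the 11 leave this difference, which largely goes with time, in place. miR-10a-5p, encoded in a HOX cluster, lay at 1562 to 5284 CPM in the 11 libraries and at 19.1 to 202 CPM in the 7. The ranges were 11486 to 30907 and 614 to 1627 CPM for miR-196a-5p, another HOX cluster miRNA, and 3638 to 9222 and 531 to 691 CPM for miR-375, a miRNA of luminal breast cells. 6 of the 9 tested luminal miRNAs had the opposite order without overlap, among them miR-342-3p (1326 to 4208 CPM in the 11, 5328 to 5920 CPM in the 7) and miR-149-5p (133 to 351 and 430 to 533 CPM).

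**Figure D1:**
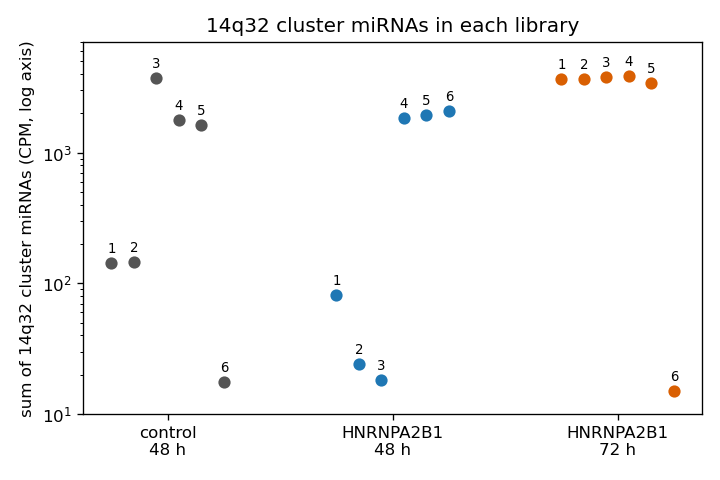
Sum of the 33 tested 14q32 cluster miRNAs in each library, in CPM on a log axis, with the 3 groups on the horizontal axis and 1 point per library marked with its replicate number. The sums lie at 1635 to 3873 CPM in 11 libraries and at 14.9 to 146 CPM in 7, and each group holds libraries of both kinds.

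At 48 h, the list of miR-17~92 and its paralogous clusters, which promote proliferation, had 5 of 13 tested members lower than in the controls and none higher (camera adjusted p = 0.000291; adjusted p = 0.3 with an estimated correlation). miR-106b-3p, the other arm of a paralogue and outside this list, was higher (log2 fold change 0.59 ± 0.12, edgeR adjusted p = 0.00753). The miR-29 family, which targets collagen and DNA methyltransferase mRNAs, had 3 of 3 lower (camera adjusted p = 0.00347; adjusted p = 0.3 with an estimated correlation). Its median log2 fold change, -0.65, was -1.02 within the 11 libraries. The 7 held no falls of the sizes found with all libraries. miR-19b-3p, of the miR-17~92 family, fell from 6026 ± 617 CPM in the controls to 3572 ± 588 CPM (SD, n = 6 each), a log2 fold change of -0.75 ± 0.10 (SE; edgeR adjusted p = 0.000296; lower than the control mean in 6 of 6 libraries). miR-4787-5p, whose precursor overlaps an exon of DOCK3 (GRCh37 chromosome 3, 50712511 to 50712594), had the largest rise among miRNAs of at least 10 CPM, from 2.32 ± 3.03 to 17.7 ± 6.29 CPM (log2 fold change 2.99 ± 0.59, edgeR adjusted p = 0.00457, 6 of 6 libraries; 3.95 without control replicate 6). In all, edgeR called 28 miRNAs higher and 27 lower of 635 tested. Of the 55 calls, 28 (50.9%) were higher, against 65.2% with upper-quartile factors and 74.2% with total counts alone.

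The other large risers of at least 10 CPM at 48 h were miR-6075, miR-3960, miR-4532, miR-4792, miR-6765-3p, miR-8086 and miR-1268a, with log2 fold changes from 2.74 for miR-6075 to 1.48 for miR-1268a. miR-4792 was the most abundant of them, at 1164 ± 507 CPM against 303 ± 317 CPM in the controls (log2 fold change 1.94 ± 0.55, edgeR adjusted p = 0.0355). miR-3960, whose precursor overlaps CDK9 (GRCh37 chromosome 9, 130548112 to 130548202), was at 108 ± 31.0 CPM against 23.0 ± 32.6 CPM. miR-1268a shares nearly all its sequence with miR-1268b, so its reads may be split between both. Control replicate 6 stood apart from the other controls for miR-6075, miR-3960 and miR-4792, with 902 CPM of miR-4792 where the other 5 had 50.9 to 368 CPM, and for miR-4787-5p, at 8.37 CPM against 0.392 to 2.06 CPM. Without it the log2 fold changes were 4.34 for miR-6075, 3.95 for miR-4787-5p, 3.43 for miR-3960, 2.84 for miR-4532 and 2.67 for miR-4792. The calls of miR-6075, miR-3960, miR-4792 and miR-4532 ended when 1 of 9, 8, 6 and 5 of the 18 libraries, respectively, was left out (highest edgeR adjusted p of 0.0875, 0.0875, 0.0915 and 0.0722). All 4 depended on controls 4 and 5 and 48 h replicates 4 and 6. All but miR-4532 depended also on control 3 and 48 h replicate 5, all but miR-4792 on control 1, miR-3960 on control 2 and miR-6075 on 48 h replicates 2 and 3. The same 4 calls ended when the 72 h libraries were kept out of the fit (edgeR adjusted p from 0.103 to 0.119).

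The largest faller among miRNAs of at least 10 CPM at 48 h was miR-135a-5p, at 116 ± 39.5 CPM against 545 ± 518 CPM in the controls (log2 fold change -2.24 ± 0.49, edgeR adjusted p = 0.00957, 0.0524 with the 72 h libraries kept out of the fit). The precursor of the entry kept for it, mir-135a-1, lies in an intron of GLYCTK-AS1 (GRCh37 chromosome 3, 52328235 to 52328324). Its reads do not show whether another precursor also gave rise to them. Over the 7 libraries of the split, miR-135a-5p lay at 145 to 235 CPM, and over the 11 at 74.2 to 1238 CPM. The 7 include 3 controls and 3 libraries at 48 h, so they held no fall of this size. miR-98-3p and let-7f-2-3p, passenger strands from precursors in introns of HUWE1 on chromosome X, fell by 0.71 and 0.69 on the log2 scale. let-7i-3p and miR-17-5p each fell by 0.70. With the 72 h libraries kept out of the fit, the calls of let-7i-3p (0.0904 in edgeR), miR-29a-3p (0.0901), miR-29c-3p (0.147), miR-20a-5p (0.0657), miR-30e-5p (0.23), miR-203a-3p (0.104) and miR-132-3p (0.0735) ended too.

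In the miR-17~92 list, miR-19a-3p (log2 fold change -0.64 ± 0.12, edgeR adjusted p = 0.0044) and miR-20a-5p (-0.57 ± 0.14, edgeR adjusted p = 0.0194) were also lower, as was miR-106a-5p (-0.46 ± 0.14, edgeR adjusted p = 0.0472). The list had 5 members lower adjusted over the list alone, and all 13 log2 fold changes were negative. camera tested 20 lists and placed this one below the other miRNAs. In the miR-29 family, miR-29a-3p (-0.91 ± 0.23), miR-29b-3p (-0.65 ± 0.12) and miR-29c-3p (-0.32 ± 0.07) were lower, and adjusted over the list alone all 3 were. Over the 7 libraries of the split, miR-29a-3p lay at 952 to 1136 CPM and miR-29b-3p at 3464 to 4420 CPM. There miR-29c-3p lay at 3279 to 3757 CPM. The 7 include 3 controls and 3 libraries at 48 h, so they held no falls of those sizes. Over the 11 the ranges were 797 to 2752, 2681 to 6713 and 2622 to 4256 CPM. Of the 5 miR-30 miRNAs, regulators of epithelial differentiation, miR-30c-5p (-0.48 ± 0.09) and miR-30e-5p (-0.23 ± 0.06) were lower, and 3 were adjusted over the list alone (camera adjusted p = 0.0197; adjusted p = 0.3 with an estimated correlation). The median of each of these 3 lists kept its sign under every scaling tried. Left-out libraries ended the calls of miR-20a-5p (controls 4 and 5 and 48 h replicate 6, edgeR adjusted p up to 0.0579), miR-29a-3p (controls 4 and 5, edgeR adjusted p up to 0.0579) and miR-30e-5p (48 h replicate 4, edgeR adjusted p = 0.0529).

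Among miRNA annotations that overlap other RNAs, such as ribosomal and small nucleolar RNA, 1 of 18 members was higher and none lower, miR-1285-5p (log2 fold change 0.98 ± 0.26, at 2.73 ± 0.831 CPM and named after its value was seen), and 1 was adjusted over the list alone (camera adjusted p = 0.0204, direction up; adjusted p = 0.3 with an estimated correlation). miR-6087 of this list was at 114 ± 52.8 CPM against 26.3 ± 50.0 CPM (edgeR adjusted p = 0.149), and without control replicate 6 its log2 fold change went from 2.13 to 4.25 and its edgeR adjusted p was 2.77e-05. Control replicate 6 was singled out here because its value stood apart, so the smaller p does not back a rise. Of 9 luminal breast miRNAs, whose median was positive (0.05) where camera's direction was down, 2 were lower, miR-203a-3p (log2 fold change -0.55 ± 0.15, edgeR adjusted p = 0.0295) and miR-29c-3p, and 2 were adjusted over the list alone. Of 6 inflammation and stress responsive miRNAs, miR-132-3p, a neuronal and immune miRNA, was higher (0.55 ± 0.15, edgeR adjusted p = 0.0295), also adjusted over the list alone. Leaving out 1 library ended the miR-132-3p call in 9 cases (controls 1 to 5 and 48 h replicates 1 to 4, edgeR adjusted p up to 0.0678) and the miR-203a-3p call in 6 (controls 3, 4 and 5 and 48 h replicates 1, 2 and 3, edgeR adjusted p up to 0.0836).

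edgeR called no member of the other 16 lists at 48 h. These were the 14q32 cluster (33 tested), oncogenic (11), tumour-suppressive (10) and p53-induced (5) miRNAs, the let-7 (9), miR-15/16 (7) and miR-200 (5) families, the miR-23/27/24 clusters (5), the clusters of miR-183, miR-96 and miR-182 (3) and of miR-221 and miR-222 (2), mirtrons (8), ESR1-targeting (6) and exosome-sorted (1) miRNAs, and markers of blood and liver (4), of mesenchymal cells (4) and of muscle, neurons and pluripotent cells (3). The let-7 median was positive (0.01) where camera's direction was down, and the mirtron median negative (-0.08) where it was up. Of their 103 distinct members, 12 had an unadjusted p under 0.05, DESeq2 called 2 and limma-voom 1. Adjusted over the list alone, 2 miR-15/16 members and 1 p53-induced member were lower. miR-21-5p was at 483042 ± 127335 CPM against 465953 ± 181033 CPM, a difference within the spread of the libraries (log2 fold change 0.05 ± 0.33, edgeR adjusted p = 0.981).

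The count of calls at 48 h depended on which libraries entered the fit. Within the 11 libraries with much 14q32 miRNA (3 controls and 3 HNRNPA2B1 libraries at 48 h), edgeR called 115 miRNAs higher and 108 lower, which included all 28 and 27 of the calls above. Within the 7 others (3 and 3 at 48 h), edgeR, the only tool run there, called 0 higher and 0 lower, with 91 miRNAs at an unadjusted p under 0.05. For the miR-29 family and miR-135a-5p, the ranges above show no falls of the reported sizes in these 7. The ranges of miR-17-5p (435 to 832 CPM) and miR-19a-3p (1359 to 2429 CPM) over the 7 leave room for theirs. With a term for this split of the libraries, the counts were 67 and 69, and without controls 3 and 6 and 72 h replicate 6 they were 65 and 58. Leaving out 1 library gave 16 (control 5) to 54 (control 6) higher, with 18 without control 4 or 48 h replicate 6. It gave 15 (control 5) to 42 (control 6) lower, with 17 without 48 h replicate 6.

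**Figure D2:**
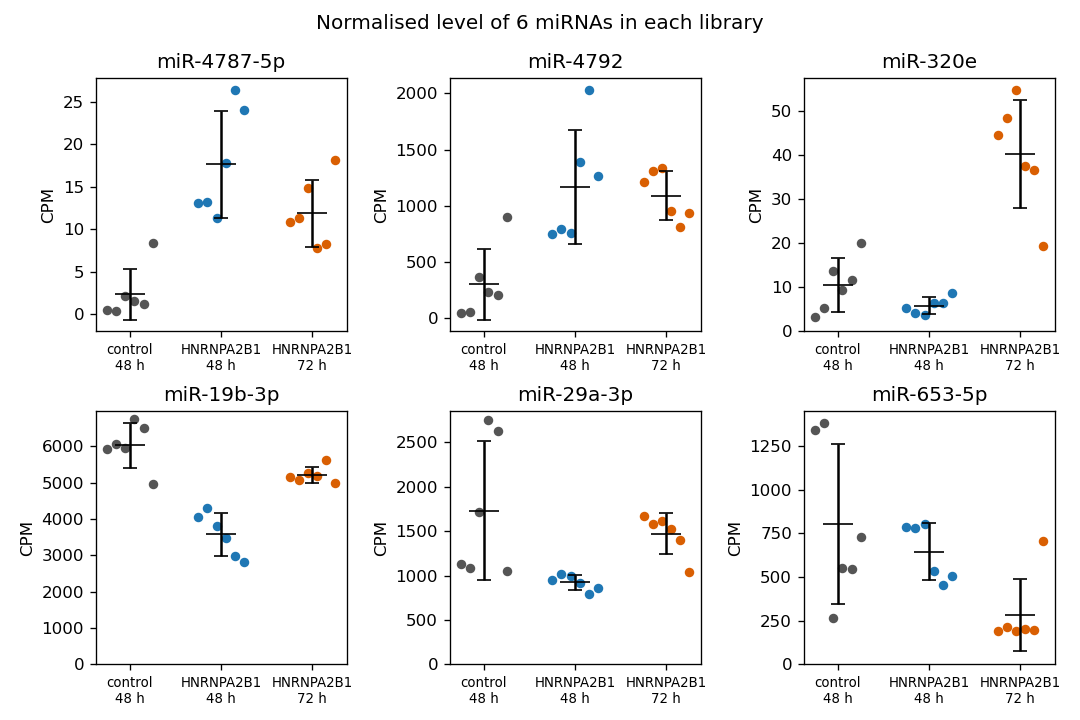
Normalised level in CPM (vertical axes, linear) of 6 miRNAs in each library, by group (horizontal axes); points are libraries, and the black bars are the group mean ± SD (n = 6). miR-4787-5p and miR-4792 lie higher in both HNRNPA2B1 groups with control replicate 6, the last grey point, among them; miR-320e lies at 40.3 ± 12.3 CPM at 72 h against 5.85 ± 1.87 CPM at 48 h.

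At 72 h, HNRNPA2B1 cells held more of miR-320b to miR-320e, of a family linked to Drosha-independent processing, and less of the 2 miR-653 arms, miR-27b-3p, miR-24-3p and miR-200c-3p than the 48 h controls. miR-320e, from an intron of PRKD2 (GRCh37 chromosome 19, 47212550 to 47212602), was at 40.3 ± 12.3 CPM against 10.5 ± 6.12 CPM (SD, n = 6 each; log2 fold change 1.94 ± 0.37, edgeR adjusted p = 0.0102, higher in 6 of 6 libraries). miR-653-3p and miR-653-5p, from an intron of the calcitonin receptor gene CALCR (GRCh37 chromosome 7, 93112072 to 93112167), were both lower: miR-653-3p fell by 1.51 on the log2 scale, and miR-653-5p went from 803 ± 458 to 283 ± 206 CPM. Both arms lay lower in the 11 libraries with much 14q32 miRNA, which hold 5 of 6 libraries at 72 h and 3 of 6 controls, than in the 7: miR-653-5p at 191 to 553 against 704 to 1382 CPM, and miR-653-3p at 238 to 677 against 796 to 1732 CPM. With the term for the split the log2 fold changes were -1.14 for miR-653-5p and -1.13 for miR-653-3p, and edgeR still called both. This term does not separate the lower from the upper level of 14q32 miRNA within the 11. edgeR called 36 miRNAs higher and 62 lower. The share of higher calls, 36.7%, was 52.6% with relative log expression factors, 8.14% with upper-quartile factors and 82.9% with total counts alone, which moved the median log2 fold change of all miRNAs by 0.10, -0.31 and 0.39. Because the control was collected at 48 h, this comparison cannot tell the plasmid from the time in culture.

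Among the largest risers of at least 10 CPM at 72 h, miR-4787-5p (log2 fold change 2.41 ± 0.58, edgeR adjusted p = 0.0152), miR-4792 (1.85 ± 0.55, 0.033 in edgeR) and miR-4532 (1.78 ± 0.55, 0.0395 in edgeR) had also risen at 48 h. miR-1261 (1.52 ± 0.38) and miR-3182 (1.51 ± 0.40), the latter from an intron of CDH13, were higher too. The list of mirtrons and other Drosha-independent miRNAs had 4 of 8 tested members higher and none lower, and 4 adjusted over the list alone: miR-320e, miR-320d (1.09 ± 0.23), miR-320c (0.91 ± 0.20) and miR-320b (0.82 ± 0.19). miR-320a, the most abundant of the family at 427 ± 70.6 CPM, differed from its 402 ± 64.6 CPM in the controls by less than the spread of the libraries. camera placed it above the other miRNAs (adjusted p = 0.0388; adjusted p = 0.665 with an estimated correlation), and its median was positive under every scaling. These miR-320 members differ by few bases, so the split of reads between them is uncertain. Control replicate 6 was the highest control for them, with 147 CPM of miR-320c where the other controls had 52.5 to 85.4 CPM. It also stood apart for miR-3182 (212 CPM, others 33.6 to 46.3 CPM) and miR-1261 (99.2 CPM, others 16.9 to 24.4 CPM). Without it the log2 fold changes were 3.38 for miR-4787-5p, 2.58 for miR-4792, 2.54 for miR-4532, 2.29 for miR-3182 and 2.22 for miR-1261. The calls of miR-4532, miR-4792 and miR-3182 ended when 1 of 10, 8 and 2 libraries was left out (edgeR adjusted p up to 0.0846, 0.0653 and 0.0542). For miR-3182 these were controls 1 and 2, for miR-4792 controls 1, 2, 4 and 5 and 72 h replicates 1 to 4, and for miR-4532 these 8, 72 h replicate 5 and 48 h replicate 4.

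Among the largest fallers of at least 10 CPM at 72 h, miR-4483 fell by 1.23, miR-32-3p (from an intron of TMEM245) by 1.21, miR-4680-3p by 1.20 and miR-296-3p by 1.13 on the log2 scale. miR-200a-5p, the passenger strand of an epithelial miR-200 member (GRCh37 chromosome 1, 1103243 to 1103332), was at 54.4 ± 15.3 CPM against 110 ± 23.1 CPM (log2 fold change -1.01 ± 0.17, edgeR adjusted p = 0.00663, lower in 6 of 6 libraries). miR-200c-5p, the passenger strand of a second member, fell by 0.93. The guide strands of the miR-200 family, which keep epithelial identity by repressing ZEB1 and ZEB2, had 1 of 5 lower, miR-200c-3p (-0.66 ± 0.18, edgeR adjusted p = 0.0217), and 5 adjusted over the list alone (camera adjusted p = 0.0388; adjusted p = 0.665 with an estimated correlation), but the median of the list, -0.36, was 0.00 with total counts alone. In the same way miR-200c-3p (5911 to 12937 against 13289 to 14725 CPM), miR-141-3p (39248 to 65789 against 73708 to 96215 CPM) and miR-429 (5014 to 6333 against 6729 to 7403 CPM) lay lower in the 11 libraries than in the 7. In the miR-23/27/24 clusters 2 of 5 were lower, miR-27b-3p (-0.89 ± 0.24) and miR-24-3p (-0.55 ± 0.16), and 3 adjusted over the list alone (camera adjusted p = 0.0388; adjusted p = 0.665 with an estimated correlation). Control replicate 3 stood apart for the sum of this list, at 17565 CPM where the other controls had 33568 to 36393 CPM. Without controls 3 and 6 and 72 h replicate 6 the list median went from -0.59 to -0.98. Of 9 luminal breast miRNAs 1 was lower, miR-200c-3p, and 1 adjusted over the list alone (camera adjusted p = 0.0388, direction down; adjusted p = 0.665 with an estimated correlation). In the oncogenic cluster of miR-183, miR-96 and miR-182, 2 of 3 were lower, miR-183-5p (-0.60 ± 0.13) and miR-182-5p (-0.47 ± 0.13), and 2 adjusted over the list alone. miR-182-5p also lay lower in the 11 libraries (6020 to 10048 CPM) than in the 7 (10142 to 13045 CPM). Such ranges depend on the normalisation factors, 0.82 to 1.34 in the 11 and 0.70 to 0.95 in the 7. Without them, miR-182-5p, miR-16-5p and miR-429 in 72 h replicate 6, 1 of the 7, would not lie above 72 h replicates 1 to 5. The ranges of miR-200c-3p over the 11 and the 7 would also overlap.

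In 72 h replicate 6 several of these fallers were at control levels: miR-653-5p was at 704 CPM where the other 5 libraries had 191 to 215 CPM, and miR-27b-3p at 7474 CPM where they had 3161 to 3415 CPM. The calls of miR-653-3p, miR-653-5p, miR-4483, miR-27b-3p and miR-182-5p each ended without 1 of 7 libraries (controls 1 and 2 and 72 h replicates 1 to 5; edgeR adjusted p up to 0.0741, 0.0741, 0.0781, 0.0615 and 0.0769). Those of miR-200c-5p, miR-24-3p and miR-200c-3p ended without 1 of 8, 8 and 6 libraries (edgeR adjusted p up to 0.0891, 0.0885 and 0.0609), controls 1 and 2 and 72 h replicates 1 to 4 each time, with 72 h replicate 5 and 48 h replicate 6 for miR-200c-5p and 72 h replicate 5 and control 4 for miR-24-3p.

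Smaller differences at 72 h touched abundant miRNAs. let-7f-5p (-0.38 ± 0.12, edgeR adjusted p = 0.04) and let-7i-5p (-0.32 ± 0.10, edgeR adjusted p = 0.0362), of the differentiation-linked let-7 family, were 2 of 9 members called lower, and 4 were adjusted over the list alone. With total counts alone let-7i-5p was at 0.060. The family median, -0.14, turned to 0.23 with total counts alone. miR-16-5p, 1 of 7 miR-15/16 members called lower and 1 adjusted over the list alone, was at 47472 ± 10946 CPM against 64170 ± 11243 CPM (edgeR adjusted p = 0.042). It lay at 39828 to 66753 CPM in the 11 libraries and at 69423 to 74657 CPM in the 7, and the family median was positive, 0.29 (-0.04 with upper-quartile factors). These 3 calls and that of miR-30b-5p (-0.55 ± 0.18, edgeR adjusted p = 0.0467) ended when 1 of 14, 13, 16 and 15 of the 18 libraries was left out (edgeR adjusted p up to 0.11, 0.115, 0.111 and 0.122): every library except control 3, 72 h replicate 6 and, for let-7f-5p, 48 h replicates 1 and 5, for let-7i-5p 48 h replicates 1, 4 and 5, and for miR-30b-5p 48 h replicate 5. Without 72 h replicate 6 they were at 0.000617, 0.00122, 0.00134 and 0.00122 in edgeR. That library was singled out because its values stood apart, and the 72 h libraries left all belong to the 11. Values without it, here and for miR-21-5p below, therefore do not back the falls. miR-17-5p (-0.48 ± 0.12) was the 1 lower member of 13 in the miR-17~92 list and the 1 adjusted over the list alone, and its call ended without 1 of 5 libraries (control 2 and 72 h replicates 1 to 4, edgeR adjusted p up to 0.0781). miR-30b-5p was the 1 of 5 in the miR-30 family, with 3 adjusted over the list alone. The medians of both lists turned positive with total counts alone (0.31 and 0.13), that of miR-17~92 also with relative log expression factors (0.02). miR-9-5p (-0.31 ± 0.08), a neuronal miRNA, and miR-126-3p (-0.38 ± 0.07), an endothelial miRNA from an intron of EGFL7, were lower. Both turned positive with total counts alone, and the miR-9-5p call ended without 1 of 6 libraries (control 2 and 72 h replicates 1 to 5, edgeR adjusted p up to 0.0711). miR-21-5p was at 311596 ± 195098 CPM against 465953 ± 181033 CPM (-0.58 ± 0.33, edgeR adjusted p = 0.216; 0.00805 in edgeR without 72 h replicate 6).

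miR-9-5p, miR-182-5p and miR-183-5p were the 3 of 11 oncogenic miRNAs called lower (5 adjusted over the list alone). miR-9-5p was the 1 of 6 in the inflammation list and the 1 of 3 among markers of muscle, neurons and pluripotent cells (1 and 2 adjusted over the list alone). miR-126-3p was the 1 of 10 tumour-suppressive miRNAs called lower (1 adjusted over the list alone). Among the 18 fragment annotations, with a median of 0.70 and a camera adjusted p of 0.0742, 2 were higher and 3 lower (5 and 3 adjusted over the list alone), with miR-3182 and miR-1285-5p (1.04 ± 0.25) higher and miR-1260a (-0.85 ± 0.27), miR-1260b (-0.83 ± 0.27) and miR-664b-3p (-1.11 ± 0.32) lower. miR-1285-5p and miR-664b-3p were named after their values were seen, and miR-1260a and miR-1260b may share reads. Only 1 of the 3 lower members was called with relative log expression factors or with total counts alone. The calls of this pair ended without 1 of 11 and 13 libraries (edgeR adjusted p up to 0.119 and 0.132): controls 1 and 2, 72 h replicates 1 to 5 and 48 h replicates 2, 3, 4 and 6, with also 48 h replicates 1 and 5 for miR-1260b.

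The 33 tested miRNAs of the 14q32 cluster all had positive log2 fold changes at 72 h (median 1.30), and edgeR called 0 of them, also adjusted over the list alone. camera placed the list above the other miRNAs (adjusted p = 0.00712; adjusted p = 0.856 with an estimated correlation), and its median stayed positive under every scaling. With the term for the split, which was drawn from this cluster, the median was 0.31. Their sum was 3076 ± 1508 CPM at 72 h and 1244 ± 1454 CPM in the controls (SD, n = 6; two-sided exact permutation test, p = 0.0714; 0.107 adjusted over 3 comparisons). 5 of the 6 libraries at 72 h, against 3 of the 6 controls, belonged to the 11 with much of this cluster. edgeR called no member of the 7 other lists at 72 h: p53-induced (5 tested), ESR1-targeting (6) and exosome-sorted (1) miRNAs, the miR-29 family (3), the cluster of miR-221 and miR-222 (2, both lower adjusted over the list alone) and the markers of blood and liver (4) and of mesenchymal cells (4), whose median (-0.04) was negative where camera's direction was up. Over these and the 14q32 cluster, 6 of 56 distinct members had an unadjusted p under 0.05, and DESeq2 and limma-voom called 1 each.

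The counts at 72 h rose when libraries that stood apart were left out. Without controls 3 and 6 and 72 h replicate 6, edgeR called 128 miRNAs higher and 194 lower, among them all 36 and 62 of the calls above. Within the 11 libraries the counts were 126 and 153, with the term for the split 70 and 96, and the 7 libraries hold only 1 of the 72 h group. Leaving out 1 library gave 20 (control 2) to 70 (72 h replicate 6) higher, with 21 without control 1, 57 without control 3 and 62 without control 6. It gave 19 (72 h replicate 2) to 161 (72 h replicate 6) lower, with 20 to 23 without controls 1 or 2 or 72 h replicates 1, 3, 4 or 5, 38 without 48 h replicate 6 and 98 without control 3. With the 48 h HNRNPA2B1 libraries kept out of the fit, edgeR called only miR-4800-3p and miR-4686 higher and miR-200a-5p lower, with 189 miRNAs at an unadjusted p under 0.05. The calls of the other miRNAs that the naming rule gave for this comparison then ended, with edgeR adjusted p from 0.0588 to 0.117. DESeq2 called 74 higher and 58 lower with all libraries.

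Between 48 h and 72 h of HNRNPA2B1, miR-320e and miR-7641 rose the most and miR-8086, miR-4680-3p and miR-1268a fell the most among miRNAs of at least 10 CPM. miR-320e went from 5.85 ± 1.87 to 40.3 ± 12.3 CPM (SD, n = 6 each; log2 fold change 2.78 ± 0.39, edgeR adjusted p = 0.000192, higher in 6 of 6 libraries). miR-8086 went from 28.5 ± 7.86 to 5.55 ± 2.73 CPM (-2.36 ± 0.29, edgeR adjusted p = 7.28e-05), and miR-4680-3p, whose precursor overlaps PDCD4 (GRCh37 chromosome 10, 112657848 to 112657913), from 20.4 ± 3.71 to 4.05 ± 1.44 CPM (-2.33 ± 0.27, edgeR adjusted p = 5.28e-05). edgeR called 63 miRNAs higher and 91 lower. The share of higher calls, 40.9%, was 52.6% with relative log expression factors, 11.8% with upper-quartile factors and 69.4% with total counts alone, which moved the median of all miRNAs by 0.14, -0.35 and 0.38.

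miR-135a-5p (1.63 ± 0.48), miR-424-5p (1.40 ± 0.40), a miRNA of the miR-15/16 seed family linked to cell cycle arrest, and miR-1297 (1.27 ± 0.22) were higher at 72 h, as was miR-7641 (1.67 ± 0.54), a fragment of ribosomal RNA. miR-1268a and miR-1268b, which may share reads, and miR-296-3p fell by 2.27, 2.21 and 1.73. let-7a-5p, let-7f-5p and let-7i-5p fell by 0.41, 0.39 and 0.37, and miR-16-5p by 0.48. The miR-17~92 list had 5 of 13 members higher and none lower, and 7 adjusted over the list alone (camera adjusted p = 0.0131, direction up; adjusted p = 0.688 with an estimated correlation), with a positive median under every scaling. The 14q32 cluster had 0 of 33 called with all 33 positive (camera adjusted p = 0.00107; adjusted p = 0.688 with an estimated correlation). The miR-7641, let-7f-5p, let-7a-5p and miR-16-5p calls ended without 1 of 8, 9, 9 and 5 libraries (edgeR adjusted p up to 0.0614, 0.0809, 0.104 and 0.06): for miR-7641 each 48 h library and 72 h replicates 1 and 3, for miR-16-5p 72 h replicates 1 to 5, and for both let-7 members these and 48 h replicates 1, 2, 3 and 6. In the other lists, edgeR called 4 let-7 members and 5 luminal miRNAs lower (1 luminal miRNA, miR-203a-3p, higher), and adjusted over the list alone 5 and 6 lower. The luminal members lower were miR-342-3p, miR-342-5p, miR-149-5p, miR-190b and miR-200c-3p. After normalisation, all of these lay lower in the 11 libraries with much 14q32 miRNA than in the 7 without overlap. The ranges of miR-200c-3p would overlap without the factors. The 11 hold 5 of 6 libraries at 72 h and 3 of 6 at 48 h; with the term for the split edgeR called 6 luminal miRNAs lower and 2 higher. miR-424-5p, higher at 72 h, lay higher in the 11 (1462 to 5911 CPM) than in the 7 (850 to 1305 CPM). The let-7 median, -0.33, was 0.03 with total counts alone. In the mirtron list miR-320b, miR-320c, miR-320d and miR-320e were higher and miR-877-5p lower (4 and 1 also adjusted over the list alone). In the miR-15/16 family 3 of 7 were higher and miR-16-5p was lower (3 and 1 adjusted over the list alone). The miR-29 family had 2 of 3 higher and the miR-30 family 1 of 5, each 3 adjusted over the list alone. The miR-200 family had 1 of 5 lower and 4 adjusted over the list alone. Of the fragment list 3 were higher and 3 lower, with a median of -0.07 where camera's direction was up. camera passed no list but the 14q32 cluster and the miR-17~92 list.

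Without controls 3 and 6 and 72 h replicate 6, edgeR called 147 higher and 202 lower between the times, within the 11 libraries 173 and 181, and with the term for the split 128 and 124. Leaving out 1 library gave 45 (48 h replicate 3) to 118 (72 h replicate 6) higher. It gave at least 54 lower (72 h replicate 1), with 56 to 59 without 72 h replicates 2 to 5, and 2 times the 91 of all libraries without 72 h replicate 6.

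Against the shared controls, 12 miRNAs were called in the same direction at 48 h and 72 h. miR-4787-5p, miR-4792, miR-4532, miR-106b-3p, miR-5100, miR-1285-5p, miR-4488 and miR-4800-3p were higher and miR-17-5p, let-7f-2-3p, miR-101-3p and miR-126-5p lower. miR-4800-3p and others outside the rule for named miRNAs were named after their values were seen. 3 miRNAs were called in opposite directions. Independent lists of these sizes would share 4.22 in the same direction (1.59 higher, 2.64 lower). Unchanged groups simulated against these controls shared 0 in 50 runs, and with the controls split into sets of 3 the observed overlap had a median of 1 (0 to 9 over 20 splits). That split also left 3 controls in each comparison, so it does not tell shared controls from smaller groups. The log2 fold changes of all 635 miRNAs had a correlation of 0.06 across miRNAs, which are not independent replicates, and a covariance of 0.0313, against 0.49 and 0.141 in the simulated unchanged groups. Of all miRNAs 44.6% had the same sign, against 66.1% in those groups. Over the splits of the controls, the correlation ran from -0.59 to 0.44, the covariance from -1.10 to 0.24 and the same sign from 24.7% to 64.6%. Since these values move so far with the choice of controls, the gap to the simulated groups decides nothing. Without controls 3 and 6 and 72 h replicate 6 the overlap was 58, and leaving out 1 library gave 5 (control 2) to 42 (control 6), with 6 or 7 without controls 1, 4 or 5, 48 h replicate 6 or 72 h replicates 1 to 4.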

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

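The tests of the 3 patterns below were chosen only after the results were seen, except the GC test of the 48 h risers and the counts over other splits of the libraries.

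A library stood far from the other 5 of its group in 62 of 249 groups of 6, where chance gives about 1 in 20. Of these, 45 were in 72 h replicate 6, 12 in control replicate 6, 4 in control replicate 3 and 1 in 72 h replicate 3. Values are CPM, with the range of the other 5 libraries in brackets. The normalisation factor was 0.725 in 72 h replicate 6 and 1.29 to 1.34 in 72 h replicates 1 to 5, which raises its CPM against theirs. Without the factors, its let-7a-5p, let-7f-5p, miR-16-5p, miR-30e-5p and miR-9-5p, among others, would not lie above those libraries. Above the others, 72 h replicate 6 had let-7a-5p at 24663 (14024 to 16384), let-7f-5p at 59477 (36465 to 40233) and let-7i-3p at 311 (205 to 236). In the same library were let-7i-5p at 17803 (12006 to 13617), miR-16-5p at 69423 (39828 to 45371) and miR-182-5p at 10142 (6020 to 7317). It also had miR-183-5p at 3546 (1944 to 2255), miR-200a-5p at 85.2 (45.4 to 52.8) and miR-200c-3p at 14079 (5911 to 7381). Likewise it had miR-21-5p at 709317 (219388 to 245274), miR-24-3p at 3473 (1870 to 2172) and miR-27b-3p at 7474 (3161 to 3415). Further values in it were miR-296-3p at 33.8 (11.8 to 15.99), miR-30b-5p at 3700 (1916 to 2080) and miR-30e-5p at 6627 (5991 to 6208). Among its values were miR-32-3p at 37.2 (16.2 to 22.3), miR-3960 at 145 (42.9 to 66.7) and miR-653-3p at 828 (238 to 264). Above the others, 72 h replicate 6 had miR-653-5p at 704 (191 to 215), miR-8086 at 10.8 (3.27 to 5.81) and miR-9-5p at 1158 (823 to 897). Below the others, it had let-7f-2-3p at 59.5 (others at least 73.1), miR-1297 at 26.2 (54.0 to 64.1), miR-135a-5p at 219 (352 to 413), miR-203a-3p at 7006 (8839 to 9707), miR-20a-5p at 1807 (2574 to 2782) and miR-377-3p at 0.489 (74.4 to 92.3). Lower there were also miR-431-5p at 0.245 (126 to 160) and miR-98-3p at 98.6 (164 to 178).

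Sums over lists in 72 h replicate 6 lay above the others for ESR1-targeting miRNAs at 859 (592 to 665), inflammation and stress responsive miRNAs at 712884 (221972 to 247826), the let-7 family at 120455 (80386 to 89654), luminal breast miRNAs at 31985 (26224 to 28095), markers of blood and liver at 256 (132 to 164) and markers of mesenchymal cells at 171 (129 to 139). The same held for markers of muscle, neurons and pluripotent cells at 1256 (886 to 961), the miR-15/16 family at 77673 (50454 to 54938), the cluster of miR-183, miR-96 and miR-182 at 18997 (12221 to 13787), the miR-200 family at 157201 (80446 to 89304), the miR-23/27/24 clusters at 38879 (17721 to 18685), the miR-30 family at 17123 (14244 to 14738), oncogenic miRNAs at 747763 (242301 to 267664) and p53-induced miRNAs at 12997 (8001 to 8738). The factors raised these sums too, and those of the let-7, miR-30, luminal, ESR1-targeting and mesenchymal lists, among others, would not lie above without them. The inflammation and oncogenic sums were mostly miR-21-5p (709317). The sum of markers of muscle, neurons and pluripotent cells was mostly miR-9-5p (1158). These 3 sums are therefore not separate from the outliers of those miRNAs. The sums lay below the others for the 14q32 cluster at 14.9 (3444 to 3873) and the miR-17~92 list at 22325 (33500 to 39802). Control replicate 6 lay above the other controls for miR-1261 at 99.2 (16.9 to 24.4), miR-3182 at 212 (33.6 to 46.3), miR-320b at 166 (64.0 to 93.6), miR-320c at 147 (52.5 to 85.4), miR-320d at 115 (36.7 to 62.7) and miR-3960 at 88.2 (4.44 to 22.9), and for miR-4787-5p at 8.37 (0.392 to 2.06), miR-4792 at 902 (50.9 to 368), miR-6075 at 76.9 (1.31 to 15.8), miR-6087 at 128 (1.83 to 13.4) and mirtrons and Drosha-independent miRNAs at 997 (592 to 732). It lay below them for miR-17-5p at 457 (749 to 832). Control replicate 3 stood apart for miR-24-3p at 2115 (3286 to 3844), miR-27b-3p at 3228 (7204 to 9190), miR-8086 at 16.3 (8.06 to 9.67) and the miR-23/27/24 clusters at 17565 (33568 to 36393). At 72 h, replicate 3 had miR-7641 at 195 (90.9 to 129).

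The change against the shared control differed between 48 h and 72 h for 37 of 60 miRNAs looked at, by edgeR's test of 72 h against 48 h at an adjusted p under 0.05. These 60 include miRNAs named for a large difference between the times; over all tested it was 154 of 635. The log2 change at 72 h exceeded that at 48 h for miR-30e-5p 0.18, let-7f-2-3p 0.36, miR-203a-3p 0.44, miR-20a-5p 0.48, miR-29b-3p 0.51 and miR-19a-3p 0.54. It was also larger for miR-19b-3p 0.54, miR-29a-3p 0.67, miR-320b 0.86, miR-320c 0.97, miR-98-3p 1.03 and miR-320d 1.18. It was also larger for miR-1297 1.27, miR-424-5p 1.40, miR-135a-5p 1.63, miR-7641 1.67 and miR-320e 2.78. It was smaller at 72 h, with differences of miR-8086 -2.36, miR-4680-3p -2.33, miR-1268a -2.27, miR-1268b -2.21, miR-296-3p -1.73 and miR-4483 -1.21. Negative differences were also found for miR-653-5p -1.19, miR-1260a -1.17, miR-1260b -1.17, miR-32-3p -1.13, miR-6765-3p -1.06 and miR-200a-5p -0.99. Negative differences were also found for miR-200c-3p -0.71, miR-183-5p -0.67, miR-16-5p -0.48, miR-24-3p -0.47, miR-182-5p -0.41 and let-7a-5p -0.41. Negative differences were also found for let-7f-5p -0.39 and let-7i-5p -0.37. By camera the lists that differed were the 14q32 cluster, with a median difference of 1.68, and the miR-17~92 list, with 0.48; neither held with an estimated correlation.

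The 14q32 cluster separated 11 libraries from 7 in each group. Depth was argued against: after all libraries were thinned to 3106986 counts, the lowest of the 11 sums was still 10.1 times the highest of the 7 (1429 and 141 CPM). The HNRNPA2B1 plasmid as its cause was also argued against, since 3 control libraries were among the 11. Whether 2 sources of cells or RNA were mixed in different shares cannot be told: 2.81% of miRNAs (10 of 356) had a mean in controls 4 and 5 more than 1.5 times outside the range of controls 1 to 3, but other readings of the same test gave 1.97% to 5.75%, on both sides of its bound of 5%. No biological explanation other than the plasmid was tested for this split. It ran in consecutive index primer numbers: 1 to 5, 9 to 11 and 16 to 18 for the 11, and 6 to 8 and 12 to 15 for the 7. These numbers follow the replicate numbers within each group, and whether the order of preparation accounts for the split was not tested.

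Control replicate 6 and 72 h replicate 6 lay closer to each other (chi-square per degree of freedom 12.8) than to their own groups (425 to 2507 from the other controls, 1387 to 1614 from the other 72 h libraries). An exchange of control replicate 3 and 72 h replicate 6 was argued against: control 3 lay at least 150 (to 222.1) from 72 h replicates 1 to 5, whose pairs lay at 6.84 to 60.8. Control 3 was nevertheless nearer to these than to any control (at least 1212), part of what an exchange would give. A single wrong label in the pair stays open, as its 12.8 lies within the range of the 72 h pairs. The values of these libraries therefore may not belong to their labelled groups, and the counts without them are given beside the results.

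The placed miRNAs called higher at 72 h had a higher median precursor GC content than all placed miRNAs. The GC test of the 48 h risers was void, because only 21 of 28 (75%) had a precursor placed on the genome. For 72 h, 30 of 36 risers (83.3%) were placed, with a median GC of 54.5% against 48.4% over all placed (percentile 99.3 of random sets matched on abundance). Once a GC trend per library was removed, 6 of 30 stayed called where 30 had been, as the median log2 fold change went from 1.16 to 0.58 and the SE from 0.30 to 0.40 (26 of 30 stayed positive), so a GC-linked bias may account for part of the rise. Neither more fragments of every kind nor the plasmid can be told from other causes: 3 fragment list members were called lower at 72 h but only 1 under every scaling, while the list median was 0.70 (1.21 without controls 3 and 6 and 72 h replicate 6), and control replicate 6 reached the lowest HNRNPA2B1 library for 7 of the 8 largest 48 h risers of at least 10 CPM, other controls for 2.

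Other splits of the 12 libraries of each comparison were fitted, 100 each. For 48 h against control, 1 split, the real one, gave as many miRNAs (55, highest other 20), so no other drawn split reached it. Such splits cannot exclude a chance difference in culture or preparation between the groups, as the replicates may be technical. For 72 h against control 3 splits did (real 98, highest other 197) and for 72 h against 48 h 2 (154 and 247), few of the 100 in each. The 2 and 1 that gave more put the 11 and 7 libraries more unevenly on their sides. For 72 h against control, the most uneven splits drawn gave 197, 141, 29, 18 and 0 calls. Larger counts there went mostly, though not always, with unevenness. For 72 h against 48 h, the other splits as uneven as that with 247 gave 0, so unevenness alone does not account for that count. Among the 52 and 43 splits as uneven in that division as the real one, the highest other count was 0 in both. For 72 h against control, however, more even splits gave up to 44. For the lists, 22, 21 and 43 of the 100 splits passed as many as the real 4, 5 and 2 (highest others 8, 8 and 6), so chance cannot be excluded.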

How the results depend on the processing

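The fits with a term for the split, within its 11 or 7 libraries, without controls 3 and 6 and 72 h replicate 6, and over all deposited entries were chosen after the data were seen, as were the list tests with that term or without those 3 libraries. Counts are higher and lower calls at 48 h against control, 72 h against control and 72 h against 48 h. Of the single miRNAs, settings other than left-out libraries kept the direction and the side of the threshold in 986 cases, lost the call in 234, gained it in 19 and reversed in 6. Left-out libraries gave 1125, 250, 7 and 4. Of the calls, 17 of 28 and 22 of 27, 19 of 36 and 53 of 62, and 45 of 63 and 61 of 91 had a mean of at least 10 CPM, and the others rest on fewer counts. Without a filter 18 and 11, 15 and 15, and 34 and 50 were called; the cause was not tested.

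Against 28 and 27, 36 and 62, and 63 and 91, upper-quartile factors gave 15 and 8, 7 higher, and 18 higher. Total counts alone gave 8 lower, 68 and 14, and 102 and 45, and relative log expression factors 37 lower at 72 h. DESeq2 gave 74 higher at 72 h and 105 higher between the times, limma-voom 47 higher at 48 h and 64 higher at 72 h. A filter of 10 CPM gave 17 lower at 48 h and 22 and 35 at 72 h. Only the groups compared gave 10 lower at 48 h and 2 and 1 at 72 h. An adjusted p under 0.01 left 11 and 10, 1 and 1, and 30 and 38, and a fold of at least 1.5 left 14 lower at 48 h and 33 lower at 72 h, by construction. The split term gave 67 and 69, 70 and 96, and 128 higher. Without controls 3 and 6 and 72 h replicate 6 the counts were 65 and 58, 128 and 194, and 147 and 202. These libraries were picked by their values, and without them the 72 h group cannot be told from the 14q32 level. Within the 11 libraries they were 115 and 108, 126 and 153, and 173 and 181, and within the 7, fewer in all, edgeR called 0 and 0 at 48 h. On each side the 48 h comparison set 3 controls against 3 HNRNPA2B1 libraries. Where not given by construction, the cause was not tested.

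The overlap of 12 was 6 with upper-quartile factors, 21 in DESeq2, 26 in limma-voom, 3 without a filter, 6 at 10 CPM, 1 with only the groups compared, 33 with the split term, 58 without the 3 libraries, 84 within the 11, 1 at an adjusted p under 0.01 and 7 at a fold of at least 1.5. The 1 was miR-4800-3p and the 3 were it, miR-101-3p and miR-4787-5p, named after their values were seen. Left-out libraries gave 16 to 54 higher and 15 to 42 lower at 48 h, 20 to 70 and 19 to 161 at 72 h, 45 to 118 and 54 to 1.8e+02 (2 times the 91) between the times, and 5 to 42 in the overlap. The report names the libraries.

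Of the lists, 4, 5 and 2 passed camera. With an estimated correlation 0, 0 and 0 passed, with the split term as well 0, 0 and 0, and with the split term alone 0 at 72 h. fry passed 9 at 72 h and 7 between the times, total counts alone 3 and 0, and 4 between the times passed without the 3 libraries; the cause was not tested.

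Directions reversed for miR-21-5p at 48 h (0.05), at -0.0071 without a filter, -0.15 within the 11 libraries and from -0.12 to 0.23 with libraries left out. miR-221-3p at 48 h was at 0.078 within the 7. With total counts alone at 72 h, let-7i-5p was at 0.060, miR-9-5p at 0.053 and miR-126-3p at 0.0037. The cause was not tested.

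With the replicate block, 39 miRNAs were lower at 72 h against 62 without it. The replicate numbers do not pair the libraries: same-numbered libraries had correlations from -0.91 to 0.87, 10 of 18 over 0.1, and 4 of 18 libraries correlated best with their own number. The other counts moved by at most 1.5 times under the block.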

Other observations

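The values here were picked after the data were seen, and no tests were run on them. Besides the 14q32 cluster, ranges over the 11 libraries with much of it and over the 7 others, from all 3 groups, were apart for other miRNAs. Some of these, named so in the report, were called between groups: miR-653-5p, miR-653-3p, miR-342-3p, miR-342-5p, miR-149-5p, miR-190b, miR-200c-3p, miR-16-5p, miR-182-5p and miR-424-5p. The ranges hold after normalisation, and those of miR-16-5p, miR-182-5p and miR-200c-3p would overlap without the factors. Whether others of these would also overlap was not tested. miR-135b-5p lay at 666 to 2047 CPM in the 11 and at 43.1 to 137 CPM in the 7. miR-205-5p, a miRNA of basal epithelial cells, lay at 251 to 1057 and at 35.2 to 76.2 CPM. miR-3613-5p had the opposite order, with 209 to 934 CPM in the 11 and 1472 to 1832 CPM in the 7. miR-196b-5p, of a HOX cluster like miR-196a-5p, lay at 38.7 to 200 and at 225 to 282 CPM. The ranges of miR-21-5p overlapped, at 176700 to 512607 and 423970 to 737019 CPM.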
